A study of Mus musculus with 15 samples.

How the data were processed

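RNA was measured from wild-type mouse mammary gland epithelial organoids that had been set beside beads soaked in FGF10 or BSA and cultured in DMEM/F12 with ITS, per the labels' protocols. Libraries were made with a stranded poly(A) kit, per the labels' protocols. The 15 libraries formed 5 groups of 3, namely 0 h, BSA 36 h, BSA 72 h, FGF10 36 h and FGF10 72 h. The titles of the last group give the factor as FGF0, and the treatment label, which says FGF10, was used.

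The values used were raw fragment counts per gene, deposited as 1 table written by featureCounts 2.0.1, per the file headers. Fragments were counted over exons by gene name, in pairs and without regard to strand, and fragments that matched several places or several genes were not counted, per the file headers. FastQC, cutadapt 1.9.1, HISAT2 2.2.1, HTSeq and DESeq2 with the mouse assembly GRCm39 are listed in the submitters' processing notes. The notes name HTSeq where the file headers name featureCounts, and the headers were followed. Because the counting was unstranded, antisense overlap could not be separated. The annotated span of Fgfr2 is unusually wide, and what its counts cover beyond the receptor's own exons was not checked. Paralogs such as Krt6a, Krt6b, Krt16, Krt14, Krt17, Prl2c3, Hbb-bs, H2ac11, Klk1, Klk6 and the Saa genes are uncertain, since reads shared between copies were left out. Of the gene names, 17 lay on more than 1 chromosome, with 0.00248% of counts.

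Depth ran from 11965322 to 24261233 counts per library at 0 h, 15581146 to 18732149 for BSA 36 h, 15784623 to 17763860 for BSA 72 h, 15386578 to 17408522 for FGF10 36 h and 12438853 to 16582856 for FGF10 72 h. The 54456 genes were filtered with filterByExpr (minimum count 10, minimum total 15), which removed 36316 and left 18140. Counts were scaled with TMM and given as CPM, counts scaled by the normalized library size. The main test was the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with 1 fit to the 5 groups, 10 residual degrees of freedom, a median prior of 5.03 degrees of freedom and a common biological coefficient of variation of 0.234. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 across all tested genes. Standard errors are the log2 difference over the square root of F.

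The 9 contrasts were FGF10 against BSA at each time, the change of that effect from 36 h to 72 h, each of the later groups against 0 h, and 72 h against 36 h within each arm. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with a correlation estimated from the data. The second form also takes its p from the residual degrees of freedom of the fit. A call lost there need not come from shared variation. For FGF10 against BSA at 72 h without 0 h replicate 1, the partial EMT list had an adjusted p of 0.0049 at the preset. With an estimated correlation of -0.003 it had 0.0519. The 34 lists covered EMT, epithelial and mammary lineage, other cell types, adhesion, cytoskeleton, signalling, metabolism, proliferation, stress and inflammation, and each needed at least 5 tested members. Their members, the panel of named genes, the groups, the tests and the alternatives were fixed before the data were examined. Named genes were those of the panel, the 10 largest rises and falls for FGF10 against BSA at each time, the 5 largest of each in other contrasts, and the members of lists with the smallest p, up to 4 for a called list and up to 2 otherwise. The largest changes were taken from called genes with a mean of at least 5 CPM in the higher group and no overlap between replicates, leaving out predicted, noncoding and pseudogene names. Some genes that met this rule are not reported here. A reference annotation gave the type of 17967 of the tested names, and 13472 were open to this rule. A gene at 0 counts in a group is given as at least so many fold, with 3 counts taken over that group, and a gene at 1 to 3 counts as a ratio with a 95% interval. Those limits cover counting error only, as the counts carry no molecular tags.

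The alternatives were DESeq2 size factors, no filter, a filter of at least 10 counts in at least 3 libraries, a fit with the replicate numbers as blocks, the BSA 72 h libraries 2_1 and 2_2 summed, a fit of only the groups compared, limma voom with sample weights, the Wald test of DESeq2 1.42.0, an estimated correlation for lists, and leaving out 1 library at a time. Chosen after the data were seen were the fits without 0 h replicate 1 for comparisons that do not use it, the list tests for several of these settings, and the list test of the change between times. The 2_1 and 2_2 libraries were checked for being repeat runs of 1 sample. Their counts differed by a mean chi-square of 4.72 per gene over 17121 genes, against 10.5 for the next closest pair of that group, so they were kept as separate libraries. This excludes repeat runs of 1 library but not several libraries of 1 culture, in which case BSA 72 h would hold 2 separate samples and not 3.

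The main test was tested on simulated data made from these libraries for FGF10 against BSA at 72 h. It found 43 of 100 genes planted at 2-fold and 72 of 100 at 4-fold, with 5 unchanged genes called. Limma voom found 41 and 71 with 4 unchanged, and DESeq2 54 and 81 with 30 unchanged. With nothing planted 1 gene and 0 lists were called. Each gene was simulated independently, so this says little about false list calls among genes that vary together. Splits of the real libraries of this comparison that mixed FGF10 with BSA called a median of 13 lists. Such splits keep part of the real difference, so this is not a rate of false calls. Nothing in the labels says that replicates were separate cultures or animals, so each p measures only the spread between these samples. Organoid outgrowth and images of migration are not given in the sources used here.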

Results

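The series asked whether mammary epithelium passes through an epithelial-mesenchymal transition (EMT) while it migrates as a group. Wild-type mouse mammary organoids were set beside beads soaked in FGF10 or in bovine serum albumin (BSA), and RNA was sequenced at 0 h, 36 h and 72 h. Each of the 5 groups held 3 libraries of 11965322 to 24261233 assigned fragments, and 18140 of 54456 genes were tested. The leading component of log2 CPM (41.5% of the variance) set the 0 h libraries (-120.9 to -95.1) apart from all later ones (-6.06 to 51.5). The next (19.2%) set FGF10 36 h (35.8 to 56.4) apart from BSA 72 h (-67.05 to -60.8). Correlations of log2 CPM within groups ran from 0.956 to 0.988. Mitochondrial transcripts made up 2.31±0.245% of counts at 0 h, 2.68±0.711% with BSA and 2.89±1.56% with FGF10 at 36 h, and 2.45±0.21% with BSA and 4.31±0.363% with FGF10 at 72 h (mean±SD, n = 3). FGF10 36 h replicate 4 stood apart, with 1.11% mitochondrial counts and a score of 63.6 on the component that held 7.04% of the variance, where the other libraries lay between -37.03 and 27.97.

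With FGF10 for 36 h, Cdh2, which encodes N-cadherin, rose 4.31-fold over BSA (log2 difference 2.11±0.44, mean±SE, adjusted p = 0.023), from 1.42±0.687 to 6.15±1.72 CPM (mean±SD, n = 3 and 3). Cdh1, which encodes E-cadherin, stood at 282±77.7 CPM with FGF10 and 218±21.4 with BSA (0.37±0.18, adjusted p = 0.29). The epithelial adhesion gene Epcam stood at 2301±535 and 2007±124 CPM (adjusted p = 0.591). The matrix gene Tnc rose 4.54-fold (adjusted p = 0.00506) and Pdpn, a membrane glycoprotein linked to cell motility, rose 3.38-fold (adjusted p = 0.00213). Of the regulators that drive EMT, none passed: Snai2 stood at 68.5±19.2 CPM with FGF10 and 56.5±6.1 with BSA (adjusted p = 0.474), and Zeb2 at 0.903±0.2 and 1.79±0.931 CPM (adjusted p = 0.32). Snai1 (-0.69±0.59, adjusted p = 0.56), Zeb1 (-0.81±0.98, adjusted p = 0.691), Vim (0.84±0.38, adjusted p = 0.262) and Fn1 (-0.25±0.36, adjusted p = 0.752) did not pass, and Twist1 had 3 counts with FGF10 and 11 with BSA (adjusted p = 0.306). The Cdh2 call was the least firm of these, with an adjusted p from 0.00022 in DESeq2 to 0.106 over the alternatives. Its adjusted p was 0.0771 with only the groups compared in the fit, 0.0712 without BSA 36 h replicate 2, 0.106 without BSA 36 h replicate 3 and 0.0764 without FGF10 36 h replicate 1.

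**Figure D1:**
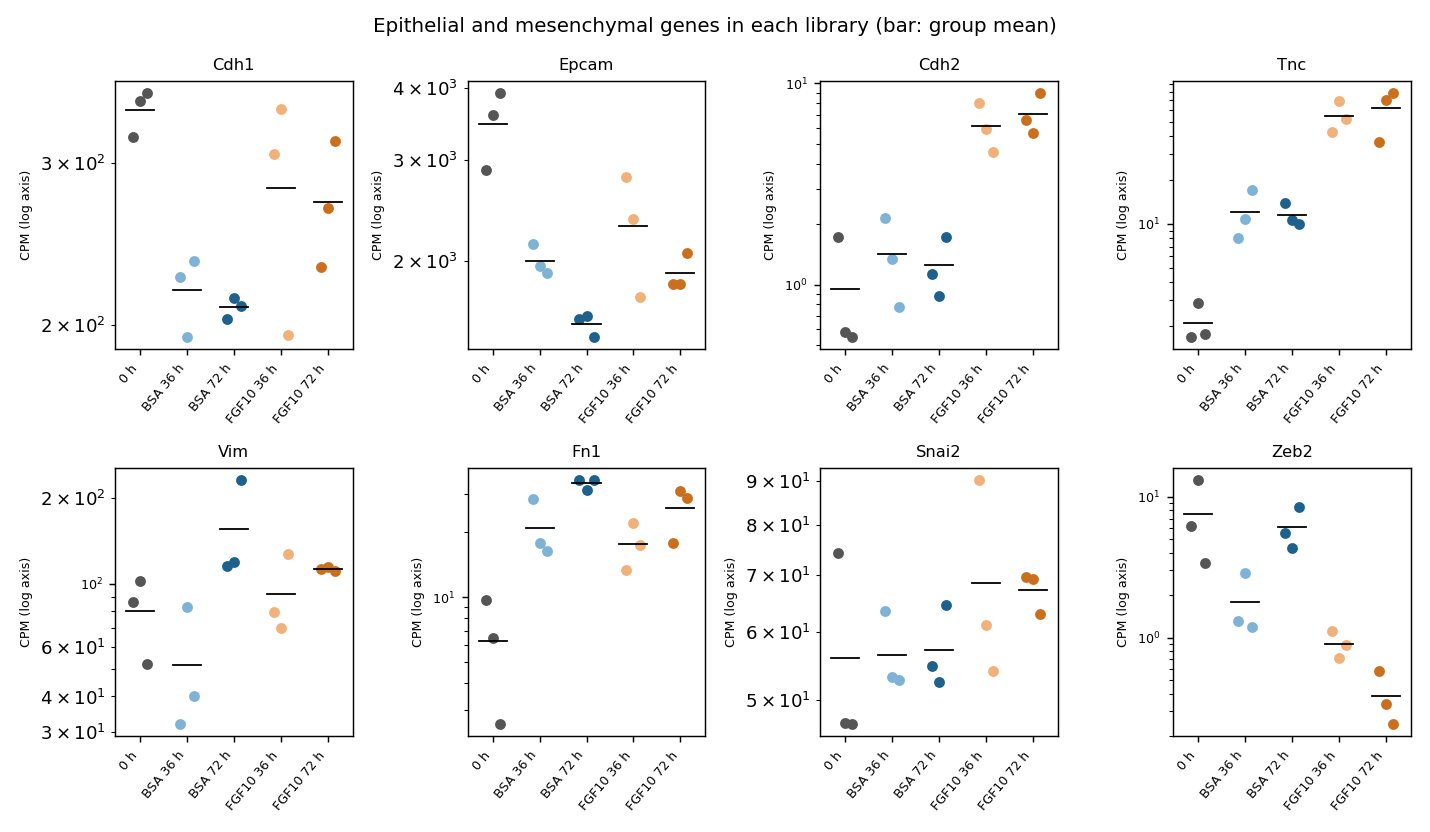
Counts scaled to library size (CPM, log axis) of Cdh1, Epcam, Cdh2, Tnc, Vim, Fn1, Snai2 and Zeb2 in each library of the 5 groups, where each mark is 1 library and each bar a group mean (n = 3). Cdh2 stood at 1.42 CPM with BSA and 6.15 with FGF10 at 36 h, while Cdh1 stood at 218 and 282.

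The partial EMT list rose (adjusted p = 0.000165), and kept its call with an estimated correlation (adjusted p = 0.0343), but not when 0 h replicate 1 was also left out (adjusted p = 0.0704). Of its 25 members 4 rose, 0 fell and 21 did not pass, or 6 and 0 adjusted over the list alone. Among its movers were Pdpn, the actin-associated Fhl2 (1.01±0.16, adjusted p = 0.00666) and the laminin chain Lama3 (0.77±0.17, adjusted p = 0.0254). The list of EMT transcription factors was not called (adjusted p = 0.455), and of 16 members 0 rose and 0 fell, or 1 and 1 adjusted over the list alone, where Tead1 had an adjusted p over all genes of 0.0504 and Tcf4 of 0.0677. Epithelial junction genes had a median of 0.04 with 0 of 40 passing (adjusted p = 0.834), Dsp lying closest (0.67, adjusted p = 0.0801). Mesenchymal effectors were called up (median 0.27, adjusted p = 0.000365, but adjusted p = 0.191 with an estimated correlation). Of 34 members 6 rose, among them Pdpn, Tnc, the protease inhibitor Timp1 (1.30±0.25, adjusted p = 0.0141) and the receptor tyrosine kinase Axl (0.62±0.13, adjusted p = 0.0229), and the matrix protease Mmp2 fell (-1.39±0.30, adjusted p = 0.026).

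Adhesion and cytoskeleton lists rose with FGF10 at 36 h and kept their calls with an estimated correlation, though not when 0 h replicate 1 was also left out (adjusted p = 0.0779 for each). Basement membrane and matrix adhesion genes (median 0.25, adjusted p = 2.7e-07, or 0.047 with an estimated correlation) had 8 of 33 members rising and 0 falling. These included the integrin chains Itga3 (1.28±0.16, adjusted p = 0.00141) and Itga2 (1.00±0.15, adjusted p = 0.00423), the collagen Col18a1 (1.73±0.24, adjusted p = 0.00268) and the integrin activator Fermt1 (1.30±0.22, adjusted p = 0.00716). Actin and motility genes (median 0.31, adjusted p = 1.3e-06, or 0.047 with an estimated correlation) had 5 of 40 rising and 0 falling, with Tpm4 at 0.83±0.15 (adjusted p = 0.01), Flna at 0.69±0.15 (adjusted p = 0.0244) and Myh10 at 0.84±0.19 (adjusted p = 0.0355).

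Cholesterol synthesis genes rose, with 9 of 24 passing upward and 0 downward, or 19 and 0 adjusted over the list alone (median 0.62, adjusted p = 1.0e-19, or 0.047 with an estimated correlation). The sterol oxidase Msmo1 rose by 1.11±0.14 (adjusted p = 0.00141) from 91.97±12.7 to 198±22.4 CPM, and the synthase Fdps by 1.11±0.21 (adjusted p = 0.0138). Fatty acid synthesis genes were also called up (median 0.16, adjusted p = 0.024, but 0.296 with an estimated correlation), with Fasn (0.89±0.16, adjusted p = 0.00935) and Elovl6 (1.10±0.20, adjusted p = 0.0103) the 2 of 20 that rose. That list call was lost without BSA 36 h replicate 2 (adjusted p = 0.0697), BSA 36 h replicate 3 (0.122) or FGF10 36 h replicate 1 (0.0713). Glycolysis and hypoxia genes were called down (median -0.59, adjusted p = 2.2e-08, but 0.323 with an estimated correlation). Of 30 members 3 fell, the phosphofructokinases Pfkl (-0.94±0.18, adjusted p = 0.0163) and Pfkp (-0.71±0.15, adjusted p = 0.0234) and the kinase Pdk1 (-0.94±0.21, adjusted p = 0.0273).

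Targets of FGF signalling moved in part. The ETS factor Etv4 rose 2.94-fold (1.55±0.32, adjusted p = 0.023) and the ERK phosphatase Dusp6 2.19-fold (1.13±0.23, adjusted p = 0.0196), while Etv5 (0.89±0.29, adjusted p = 0.117), Spry4 (0.92±0.28, adjusted p = 0.093) and Spry2 (0.03, adjusted p = 0.98) did not pass. The Etv4 call was lost without BSA 36 h replicate 2 (adjusted p = 0.0662), BSA 36 h replicate 3 (0.101), FGF10 36 h replicate 1 (0.07) or FGF10 36 h replicate 3 (0.0501). That of Dusp6 was lost without BSA 36 h replicate 2 (adjusted p = 0.0709), BSA 36 h replicate 3 (0.0519) or FGF10 36 h replicate 1 (0.0671). The FGF and ERK feedback list was called up (2 of 29 rose, adjusted p = 0.00159, but 0.329 with an estimated correlation and 0.059 without FGF10 36 h replicate 3). Fgfr2, the receptor that binds FGF10, stood level (0.09±0.20, adjusted p = 0.833), and the list of FGF receptors and ligands was not called (adjusted p = 0.704), though Sdc1, a heparan sulfate proteoglycan, rose by 1.30±0.18 (adjusted p = 0.00272) from 193±11.8 to 477±44.5 CPM.

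Among the largest rises at 36 h, R3hdml rose 21.6-fold (4.43±0.54, adjusted p = 0.00213), the cytokine Tslp 9.6-fold (3.26±0.47, adjusted p = 0.00332) and the cytokine Il24 8.1-fold (adjusted p = 0.0244). The transcriptional coactivator Pou2af1 rose 7.39-fold (adjusted p = 0.00206) and the kinase Prkg2 6.04-fold (adjusted p = 0.00272). Serpinb2, Sox15 and Plac8 were also among them, with Tnc. Among falls, Acsl6 had 2 counts with FGF10 and 270 with BSA, a ratio of 129.4 (95% interval 35.49 to 1074, counting error only, adjusted p = 0.00014). The chemokines Cxcl13 (-4.97±0.73, adjusted p = 0.00714) and Cxcl12 (-3.25±0.63, adjusted p = 0.0234) fell, as did the cornified envelope genes Ivl (-4.71±1.02, adjusted p = 0.0384), Lor (-3.68±0.64, adjusted p = 0.0112) and Lce6a (-4.27±0.97, adjusted p = 0.0456), with Klk1, Vstm2b, Prrt1 and Cck. The Cxcl13 call was lost in limma voom (adjusted p = 0.0626).

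Squamous differentiation genes were nevertheless called up (median 0.60, adjusted p = 0.00016, but 0.191 with an estimated correlation). Of 21 members 5 rose and 2 fell, with the desmosomal cadherins Dsg3 (1.33±0.24, adjusted p = 0.0105) and Dsc3 (1.44±0.31, adjusted p = 0.0259) rising and Sbsn (-1.07±0.24, adjusted p = 0.0287) falling beside Ivl. The keratins of basal cells stood higher without passing, Krt14 at 4772±296 against 3096±253 CPM (adjusted p = 0.0897) and Krt5 at 1832±271 against 1263±63.7 (adjusted p = 0.0685), and both passed in limma voom and in DESeq2. Basal and myoepithelial markers were not called (3 of 29 rose and 2 fell, adjusted p = 0.0629), with the contractile actin Actg2 rising (1.17±0.24, adjusted p = 0.0205) and Igfbp5, which binds IGFs, falling (-1.85±0.30, adjusted p = 0.00646). Krt8 (0.08±0.23, adjusted p = 0.872), Krt18 (0.10±0.29, adjusted p = 0.886), Trp63 (0.52±0.16, adjusted p = 0.0957) and Acta2 (0.38±0.27, adjusted p = 0.461) did not pass.

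Proliferation lists were called up at 36 h although no member passed on its own. DNA replication genes had a median of 0.67 with 0 of 40 passing (adjusted p = 8.6e-07, but 0.672 with an estimated correlation), and mitosis genes a median of 0.82 with 0 of 40 (adjusted p = 8.1e-05, but 0.746 with an estimated correlation). Without 0 h replicate 1, 28 of the 80 members rose. Mki67 stood at 77.7±11.8 CPM with FGF10 and 45.4±12.9 with BSA (adjusted p = 0.611). Ribosome biogenesis genes were called up (median 0.27, 0 of 30 passing, adjusted p = 0.00034, but 0.438 with an estimated correlation), where Ncl had an adjusted p of 0.0882. Milk genes were called down (median -0.81, adjusted p = 0.0002, but 0.191 with an estimated correlation), with Btn1a1, a milk fat globule protein, the 1 of 10 that fell (-1.83±0.28, adjusted p = 0.00562). Markers of other cells were also called down, all of these calls being lost with an estimated correlation. Immune markers had a median of -0.59 (adjusted p = 0.00565, or 0.458 with an estimated correlation) with H2-Ab1, an antigen-presentation gene, the 1 of 18 that fell (-1.99±0.41, adjusted p = 0.0261). The immune call was lost without FGF10 36 h replicate 1 (adjusted p = 0.126) or FGF10 36 h replicate 3 (0.059). Endothelial markers had a median of -1.55 and 0 of 20 passing (adjusted p = 0.0112, or 0.706 with an estimated correlation, 0.396 without BSA 36 h replicate 2 and 0.0689 without FGF10 36 h replicate 1). Adipocyte markers had a median of -1.14 (adjusted p = 0.024, or 0.493 with an estimated correlation) with Lep, the adipokine, at 0 counts with FGF10 and 30 with BSA, at least 9.59-fold lower at the floor of 3 counts (adjusted p = 0.023). The adipocyte call was also lost without BSA 36 h replicate 2 (adjusted p = 0.202), FGF10 36 h replicate 3 (0.162), FGF10 36 h replicate 4 (0.0737) or 0 h replicate 1 (0.0501).

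The other lists were not called at 36 h. They were interferon response (adjusted p = 0.106), ribosomal protein (0.149), hormone sensing luminal (0.183), WNT targets (0.259), fibroblast and stromal (0.265), branching morphogenesis (0.44), luminal progenitor and alveolar (0.44), NOTCH (0.593), inflammatory (0.704), p53 targets (0.737), luminal (0.737) and oxidative phosphorylation genes (0.737). The same held for stress and unfolded protein response (0.868) and TGF-beta and BMP response genes (0.868). Single members did pass in some of them. The secreted Wfdc2 rose from 303.8 to 1209 CPM (1.99±0.28, adjusted p = 0.00268). Tcf7, a WNT effector, rose by 0.97±0.20 (adjusted p = 0.0234), the NOTCH ligand Jag1 by 0.86±0.17 (adjusted p = 0.0205) and the p53 target Plk2 by 1.43±0.25 (adjusted p = 0.009), while Tgfb3 fell (-0.61±0.15, adjusted p = 0.0465) with Clic6 and Atp6v1b1.

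At 36 h edgeR called 425 genes, 173 higher with FGF10 and 252 lower, of which 88 and 155 changed at least 2-fold. The count was 199 without BSA 36 h replicate 2, 127 without BSA 36 h replicate 3, 203 without FGF10 36 h replicate 1 and 852 without 0 h replicate 1. It was 78 with only the groups compared (40 higher and 38 lower), 1415 in limma voom and 1082 in DESeq2. Of 63 named genes called at 36 h, 36 lost the call when some 1 library was left out. Of the rest 20 kept it under every alternative, among them Tnc, Pdpn, Fhl2, Itga3, Col18a1, Sdc1, R3hdml, Tslp, Igfbp5 and Acsl6. In every named rise or fall the 3 FGF10 libraries lay outside the range of the 3 BSA libraries, which the naming rule required of the largest changes. Of the 16 lists called, 4 held with an estimated correlation, those of cholesterol synthesis, basement membrane, actin and partial EMT. None of them held it without 0 h replicate 1 (adjusted p from 0.0704 to 0.0782), a library outside this comparison that shares its estimate of spread.

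At 72 h Cdh2, Tnc and Pdpn rose again and Zeb2 fell. Cdh2 rose 5.64-fold over BSA (2.50±0.44, adjusted p = 0.00666), from 1.25±0.436 to 7.05±1.71 CPM (n = 3 and 3). Tnc rose 5.32-fold (2.41±0.33, adjusted p = 0.0022) and Pdpn 4.48-fold (2.16±0.24, adjusted p = 0.00059). Cdh1 stood at 272±43.2 CPM with FGF10 and 209±5.4 with BSA (0.38±0.18, adjusted p = 0.221), and Epcam at 1907±137 and 1557±68.9 (adjusted p = 0.361). Zeb2, a repressor of Cdh1 that immune and stromal cells also express, fell 15.5-fold (-3.95±0.57, adjusted p = 0.00225) from 6.11±2.13 to 0.386±0.172 CPM. Snai1 (0.49±0.56, adjusted p = 0.65), Snai2 (0.23±0.20, adjusted p = 0.526), Zeb1 (-2.36±0.84, adjusted p = 0.11), Twist1 (-1.13±0.62, adjusted p = 0.293), Vim (-0.47±0.38, adjusted p = 0.496), Fn1 (-0.38±0.36, adjusted p = 0.571) and Col1a1 (-2.34±0.88, adjusted p = 0.135) did not pass. All 3 FGF10 libraries lay outside the BSA range for each gene called here. The naming rule required this of Zeb2 as a largest fall, and called genes are prone to it, so it adds no support. The calls of Cdh2, Tnc, Pdpn and Zeb2 at 72 h held under every alternative.

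Markers of other cell types stood lower with FGF10 than with BSA at 72 h, as did Zeb2. Falls here are against BSA at the same time, and the gap went with a rise in the BSA arm after 36 h. Adipocyte markers summed to 43.53 to 94.74 CPM with BSA at 36 h and 437.2 to 449.8 at 72 h. With FGF10 they summed to 20.58 to 28.53 and 15.84 to 81.79. The FGF10 sums of immune markers also overlapped between the times, and those of endothelial and fibroblast markers were higher at 72 h. Immune markers (median -1.70, adjusted p = 1.6e-14, or 0.0462 with an estimated correlation) had 10 of 18 members falling and 0 rising, among them H2-Ab1 (-3.15±0.43, adjusted p = 0.0031), the macrophage gene Adgre1 (-2.26±0.43, adjusted p = 0.00984) and Csf1r (-1.51±0.31, adjusted p = 0.0126). Adipocyte markers (median -3.42, adjusted p = 1.4e-10, or 0.0462 with an estimated correlation) had 6 of 12 falling and all 12 adjusted over the list alone. Lpl, a lipase, stood at 15.7 CPM against 104.1 (-2.74±0.49, adjusted p = 0.0111), and the adipokine Adipoq fell 22.1-fold (adjusted p = 0.0384) from 21.2±3.98 to 0.919±1.59 CPM. Endothelial markers were called down (median -3.30, adjusted p = 5.7e-08, but 0.313 with an estimated correlation), with Pecam1, a junction protein of vessels (-3.46±0.84, adjusted p = 0.034), and Vwf (-1.85±0.50, adjusted p = 0.0498) the 2 of 20 that fell, or 15 adjusted over the list alone. Fibroblast and stromal markers were called down (median -1.35, adjusted p = 0.00046, but 0.414 with an estimated correlation), with the collagen Col5a1 falling (-1.43±0.27, adjusted p = 0.00944) and the matrix gene Fbln1 rising (1.62±0.32, adjusted p = 0.0121) among 24. The Adipoq call was lost without BSA 72 h replicate 2_1 (adjusted p = 0.101), 2_2 (0.116) or 3 (0.0971), without FGF10 72 h replicate 3 (0.0982) or 4 (0.139), and in DESeq2 (0.368). That of Pecam1 was lost without any 1 of the BSA 72 h libraries and without FGF10 72 h replicate 3 or 4 (adjusted p from 0.0613 to 0.167).

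Basal keratins rose with FGF10 at 72 h. Krt14 rose 3.26-fold (1.71±0.19, adjusted p = 0.00059) and Krt5 2.37-fold (1.24±0.15, adjusted p = 0.00061), from 1286±64.4 to 3044±199 CPM for Krt5. Squamous differentiation genes were called up (median 0.99, adjusted p = 5.7e-08, but 0.0505 with an estimated correlation), with 8 of 21 rising and 1 falling. Dsg3 rose by 2.05±0.24 (adjusted p = 0.00061), Dsc3 by 1.91±0.30 (adjusted p = 0.00391), the stress keratin Krt16 by 2.56±0.27 (adjusted p = 0.00059) and Krt6b by 2.95±0.47 (adjusted p = 0.00406). Basal and myoepithelial markers as a list were not called (5 of 29 rose and 3 fell, adjusted p = 0.237). Krt8 (0.54±0.23, adjusted p = 0.161), Krt18 (0.06, adjusted p = 0.924), Acta2 (0.04, adjusted p = 0.945) and Trp63 (0.16, adjusted p = 0.586) did not pass.

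The partial EMT list was called up again (5 of 25 rose and 0 fell, median 0.24, adjusted p = 0.00228, or 0.0462 with an estimated correlation), with Fhl2 at 1.04±0.17 (adjusted p = 0.00406). The hemidesmosomal Col17a1 (0.62±0.16, adjusted p = 0.034) and the integrin chain Itgb6 (0.97±0.26, adjusted p = 0.0413) rose beside Pdpn. Actin and motility genes rose (9 of 40, with 2 falling, median 0.28, adjusted p = 1.2e-05, or 0.0462 with an estimated correlation), with the filament-severing Cfl1 at 0.88±0.15 (adjusted p = 0.00531) and Actg1 at 1.02±0.20 (adjusted p = 0.0111). EMT transcription factors had 1 member rising (Tead1, 0.42±0.12, adjusted p = 0.0491, lost without any 1 of the 6 libraries compared, from 0.0668 to 0.198) and 1 falling (Zeb2), with a median of 0.21 where the test pointed down (adjusted p = 0.536). Mesenchymal effectors had 6 of 34 rising and 0 falling, with a median of -0.17 where the test pointed up (adjusted p = 0.127). Epithelial junction genes were not called (2 of 40 rose and 1 fell, adjusted p = 0.696), with the desmosomal Pkp1 rising (0.86±0.15, adjusted p = 0.00558) and the epithelial factor Elf3 falling (-0.94±0.18, adjusted p = 0.00944). Basement membrane genes had 5 rising and 3 falling and were not called (adjusted p = 0.13), with Col18a1 (1.87±0.24, adjusted p = 0.00115) and Itga3 (0.88±0.16, adjusted p = 0.00699) again among the rises.

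Cholesterol synthesis genes rose again (14 of 24 with 0 falling, median 0.81, adjusted p = 9.4e-19, or 0.0462 with an estimated correlation). The demethylase Cyp51 rose by 1.20±0.20 (adjusted p = 0.00505) and the sterol dehydrogenase Nsdhl by 0.83±0.14 (adjusted p = 0.00505). Fatty acid genes were called up (4 of 20 rose, adjusted p = 0.00353, but 0.143 with an estimated correlation), with Acly (1.00±0.19, adjusted p = 0.0108) and Elovl5 (0.79±0.15, adjusted p = 0.00944). WNT targets were called up (3 of 17 rose and 1 fell, median 0.47, adjusted p = 0.00086, or 0.0462 with an estimated correlation). The risers were Tcf7 (1.47±0.21, adjusted p = 0.0022) and a pair of WNT antagonists, Wif1 (2.46±0.35, adjusted p = 0.0031) and Nkd2 (1.30±0.28, adjusted p = 0.0181), while the antagonist Nkd1 fell (-1.39±0.32, adjusted p = 0.0233). Glycolysis and hypoxia genes were called down (7 of 30 fell and 2 rose, median -0.58, adjusted p = 3.6e-07, but 0.313 with an estimated correlation), with the lactate exporter Slc16a3 falling (-2.18±0.47, adjusted p = 0.0224) and the hypoxia-induced Car9 rising (1.16±0.25, adjusted p = 0.0168).

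Etv4 rose 5.66-fold at 72 h (2.50±0.35, adjusted p = 0.00194), Etv5 by 1.14±0.30 (adjusted p = 0.0376) and Dusp6 by 0.95±0.23 (adjusted p = 0.026), while the FGF and ERK feedback list as a whole was not called (3 of 29 rose, adjusted p = 0.0562). Spry2 (0.09, adjusted p = 0.928), Spry4 (-0.04, adjusted p = 0.957) and Fgfr2 (-0.24, adjusted p = 0.497) did not pass. The Dusp6 call was lost without any 1 of the BSA 72 h libraries and without FGF10 72 h replicate 3 or 4 (adjusted p from 0.0506 to 0.152), and the Etv5 call without any 1 of the 6 libraries compared (from 0.0549 to 0.185). Among the largest rises were the cytokines Il19 (18.3-fold, adjusted p = 0.00332) and Il33 (10.3-fold, 2.27±0.758 to 23.5±7.59 CPM, adjusted p = 0.0138), Slc12a3, Krt4, Nt5dc2, H2ac11, Pou2af1 and Krt6a (6.29-fold, adjusted p = 0.00822). Among the largest falls were Cxcl13 (10.5-fold, 239.6±39.2 to 22.8±12.5 CPM, adjusted p = 0.0111), the nitric oxide synthase Nos2 (-3.42±0.53, adjusted p = 0.00332), the fat droplet gene Plin1 (-4.39±1.08, adjusted p = 0.0343), and Adgrl4, Nnmt, Pkib and Lmo2. The Il33 call was lost without any 1 of the BSA 72 h libraries and without FGF10 72 h replicate 4 (adjusted p from 0.0531 to 0.075).

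**Figure D2:**
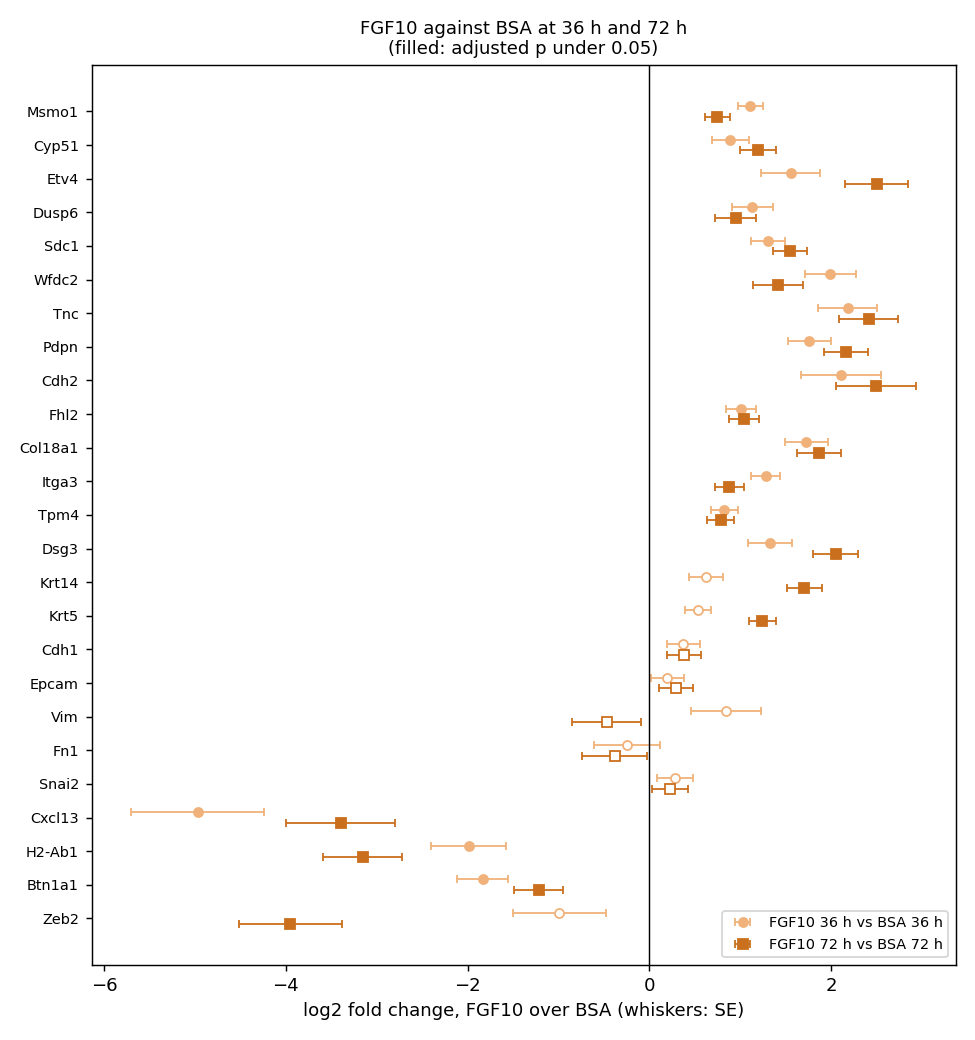
Log2 fold change of FGF10 over BSA at 36 h (circles) and 72 h (squares) for 25 genes, with bars of 1 SE and filled marks where the adjusted p was under 0.05 (n = 3 per group). Cdh2 stood at 2.11 and 2.50, Tnc at 2.18 and 2.41, and Cdh1 at 0.37 and 0.38.

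Growth-related lists were called up at 72 h, each call being lost with an estimated correlation. DNA replication genes had a median of 1.13 (adjusted p = 1.8e-12, or 0.404 with an estimated correlation), with the nuclease Fen1 the 1 that rose (1.41±0.37, adjusted p = 0.0369). Mitosis genes had a median of 1.47 (adjusted p = 2.4e-09, or 0.485 with an estimated correlation), with the kinase Aurka the 1 that rose (1.69±0.42, adjusted p = 0.0342), and Mki67 stood at 59.1 against 22.8 CPM (adjusted p = 0.305). The Fen1 and Aurka calls were lost without any 1 of the 6 libraries compared (adjusted p from 0.0572 to 0.175 for Fen1 and from 0.0577 to 0.16 for Aurka), where 0 of the 80 members of these lists rose, and with 2_1 and 2_2 summed (0.126 and 0.107). Without 0 h replicate 1, 77 of the 80 rose. Ribosomal protein genes had a median of 0.37 with 3 of 34 rising (adjusted p = 8.1e-07, or 0.404 with an estimated correlation), such as Rps2 (0.73±0.15, adjusted p = 0.0138). Ribosome biogenesis genes had 3 of 30 rising (median 0.23, adjusted p = 4.1e-05, or 0.313 with an estimated correlation), such as Dkc1 (0.74±0.15, adjusted p = 0.0135). Oxidative phosphorylation genes had Atp5pb as the 1 of 29 that rose (0.53±0.13, adjusted p = 0.0287; list adjusted p = 0.00512, or 0.632 with an estimated correlation). Stress and unfolded protein response genes were called down (median -0.19, adjusted p = 0.0114, but 0.313 with an estimated correlation), with 5 of 30 falling, such as Ddit3, a factor of stress-induced death (-1.02±0.26, adjusted p = 0.0322), and Chac1 (-1.90±0.39, adjusted p = 0.0138).

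The lists not called at 72 h beyond those above were milk (adjusted p = 0.0591), inflammatory (0.0725), NOTCH (0.105), hormone sensing luminal (0.201), branching (0.237), luminal progenitor (0.355), FGF receptors and ligands (0.421), interferon (0.499), p53 (0.536), luminal (0.544) and TGF-beta and BMP response genes (0.696). Within them the NOTCH genes Dll4 (-3.18±0.49, adjusted p = 0.00332) and Notch4 (-1.32±0.25, adjusted p = 0.0104), which vessels express, fell, and the guidance cue Slit3 fell (-2.31±0.52, adjusted p = 0.0207). Sdc1 (1.55±0.19, adjusted p = 0.00061) and Fgfbp1, which carries FGFs (1.49±0.31, adjusted p = 0.0176), rose.

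At 72 h edgeR called 1087 genes, 546 higher with FGF10 and 541 lower, of which 220 and 370 changed at least 2-fold. The count was 317 without BSA 72 h replicate 2_1, 251 without replicate 2_2, 257 without replicate 3, 559 without FGF10 72 h replicate 2, 424 without replicate 3, 148 without replicate 4 and 1857 without 0 h replicate 1. Of 96 named genes called at 72 h, 64 lost the call when some 1 library was left out. The other 32 kept it under every alternative, among them Krt14, Krt5, Dsg3, Etv4, Sdc1, Col18a1, Cxcl13 and H2-Ab1. The count of all called genes was 277 with the 2_1 and 2_2 libraries summed, as they should be if they came from 1 culture, 5025 with only the groups compared, 4824 in limma voom and 1912 in DESeq2. Of the 17 lists called, 6 held with an estimated correlation, those of cholesterol synthesis, immune, adipocyte, actin, WNT and partial EMT. No list held it without 0 h replicate 1, with an adjusted p of 0.0519 for the immune, adipocyte, WNT and partial EMT lists, 0.0686 for cholesterol synthesis and 0.0712 for actin. The DNA replication and mitosis lists shared the value of 0.0519. At the preset correlation the fit without that library kept all 17 calls.

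**Figure D3:**
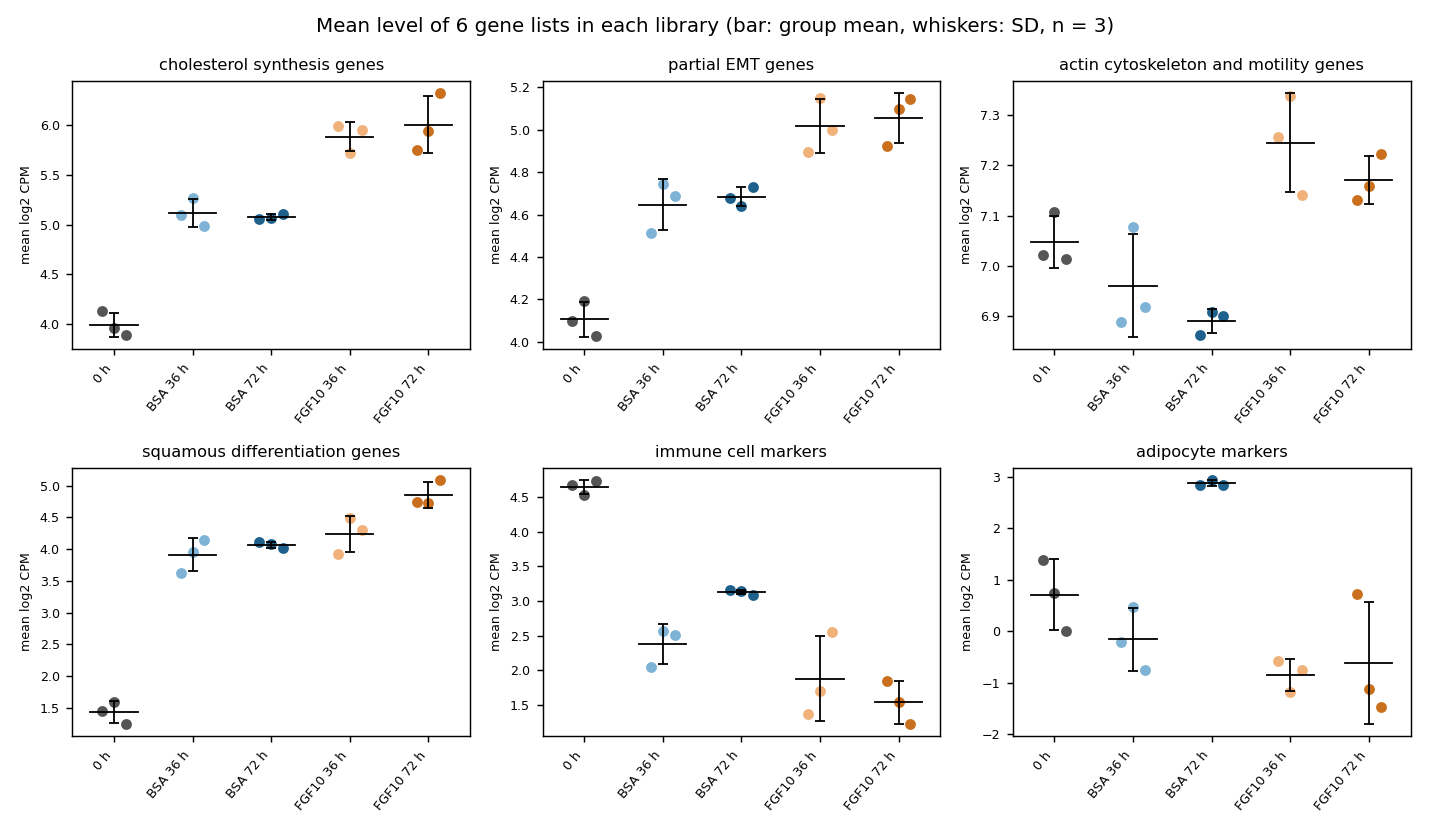
Mean log2 CPM of the members of 6 lists in each library of the 5 groups, with bars at the group mean and whiskers of 1 SD (n = 3). Immune and adipocyte markers stood lower with FGF10 than with BSA at 72 h, with list medians of -1.70 and -3.42.

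In the main test no gene's FGF10 effect was called different between 36 h and 72 h, with 0 genes called in edgeR, 998 at an unadjusted p under 0.05, 0 called in limma voom and 19 in DESeq2. Cdh2, Tnc, Pdpn and Etv4 were called higher at both times, and Cxcl13, Tgfb3 and Btn1a1 lower at both. Of genes called higher, 105 were shared between the times (5.21 expected by chance), of genes called lower 124 (7.52 expected), and 0 were called in opposite directions (12.7 expected). Of the 425 genes called at 36 h, 412 had the same sign at 72 h, and the effects of all tested genes at the different times had a correlation of 0.602. These comparisons share no libraries, but they share the estimate of spread of each gene. The numbers expected by chance hold only for independent calls, so no p is given for the overlap. In simulated data the test of this change found 12 of 100 genes planted at 2-fold and 49 of 100 at 4-fold, so that smaller differences would mostly be missed.

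Between 0 h and 36 h with BSA, Cdh1 fell from 343±20.1 to 218±21.4 CPM (-0.65±0.18, adjusted p = 0.0151, n = 3 and 3) and Epcam fell by 0.79±0.18 (adjusted p = 0.00539) from 3464±530 CPM, with the claudin Cldn3 (-1.30±0.14, adjusted p = 1.8e-05). Snai1 rose from 0.148±0.0566 to 1.09±0.862 CPM (2.93±0.74, adjusted p = 0.00836) and the matrix gene Fn1 from 6.25±3.55 to 20.9±6.67 (1.73±0.38, adjusted p = 0.00463). Zeb1 (-2.45±0.82, adjusted p = 0.0398), Zeb2 (-2.06±0.47, adjusted p = 0.00466), Pdgfra (-2.12±0.39, adjusted p = 0.001) and Col1a1 (-3.31±0.84, adjusted p = 0.0117) fell, while the others did not pass, Cdh2 at 0.49±0.47 (adjusted p = 0.472), Snai2 at 0.01±0.20 (adjusted p = 0.98) and Vim at -0.63 (adjusted p = 0.245). The Cdh1 call was lost without BSA 36 h replicate 2 (adjusted p = 0.0608), as was that of Snai1 (0.054), and the Col1a1 call without BSA 36 h replicate 3 (0.052). The Zeb1 call was lost without 0 h replicate 1 (adjusted p = 0.0821), 0 h replicate 2 (0.109), BSA 36 h replicate 1 (0.113) or BSA 36 h replicate 3 (0.119). Fgfr2 fell from 516±106 to 71.3±5.35 CPM (-2.86±0.21, adjusted p = 5.5e-07). The immediate early genes Fos (-7.57±0.52, adjusted p = 5.5e-07), Fosb (-8.76±0.60, adjusted p = 1.3e-06) and Egr1 (-4.30±0.45, adjusted p = 1.9e-05) fell, Fos from 12530±8363 to 65.8±10.7 CPM.

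By 36 h with BSA the metabolic and squamous lists had risen, though all 18 list calls of this comparison were lost with an estimated correlation. Glycolysis and hypoxia genes had 25 of 30 rising and 2 falling (median 1.82, adjusted p = 2.1e-20, or 0.097 with an estimated correlation), with Ldha, which makes lactate, up by 2.69±0.24 (adjusted p = 2.7e-06). Cholesterol genes had 19 of 24 rising (adjusted p = 3.9e-13, or 0.102 with an estimated correlation), with Msmo1 at 1.54±0.14 (adjusted p = 2.7e-06). Squamous genes had 16 of 21 rising (adjusted p = 1.2e-10, or 0.097 with an estimated correlation), with Krt16 at 3.82±0.31, and Krt5 (1.84±0.15, adjusted p = 1.4e-06) and Krt14 (1.96±0.19, adjusted p = 4.9e-06) rose. Inflammatory genes had 15 of 34 rising (adjusted p = 6.9e-05, or 0.507 with an estimated correlation), with the prostaglandin synthase Ptgs2 at 5.78±0.84 (adjusted p = 0.00046). Partial EMT genes had 7 of 25 rising and 2 falling (adjusted p = 0.0161, or 0.097 with an estimated correlation), with the thrombospondin Thbs1 (2.13±0.32, adjusted p = 0.00027) and Inhba (2.40±0.39). Fatty acid genes were called up (8 rose, 1 fell, adjusted p = 0.00023, or 0.097 with an estimated correlation), as were ribosome biogenesis genes (15 rose, adjusted p = 0.00023, or 0.451 with an estimated correlation). Interferon genes were called up (13 rose, 4 fell, adjusted p = 0.0135, or 0.642 with an estimated correlation). Mitosis genes (0 rose, adjusted p = 1.4e-05, or 0.595 with an estimated correlation) and DNA replication genes (0 rose, adjusted p = 0.00034, or 0.642 with an estimated correlation) were also called up. Of the 80 members of these lists 79 rose without 0 h replicate 1, and 72 in limma voom.

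Immune markers fell from 0 h to 36 h with BSA, 15 of 18 with 1 rising (median -3.03, adjusted p = 5.8e-13, or 0.097 with an estimated correlation), Cd74, which chaperones antigen-presenting complexes, going from 1214±194 to 47±7.46 CPM (-4.69±0.28, adjusted p = 1.3e-07). Fibroblast markers had 15 of 24 falling (adjusted p = 4.5e-05, or 0.451 with an estimated correlation), such as Dcn (-3.03±0.53, adjusted p = 0.00139). Endothelial markers had 9 of 20 falling (adjusted p = 0.00021, or 0.451 with an estimated correlation), such as Vwf (-3.09±0.48, adjusted p = 0.00051). Hormone sensing genes had 8 of 19 falling (adjusted p = 0.00034, or 0.307 with an estimated correlation), such as the prolactin receptor Prlr (-2.18±0.37, adjusted p = 0.00063). FGF and ERK feedback targets had 12 of 29 falling and 6 rising (adjusted p = 0.00507, or 0.448 with an estimated correlation), with Dusp6 at -2.23±0.23 (adjusted p = 1.1e-05). Basal markers were called down (14 fell, 5 rose, adjusted p = 0.0115, or 0.307 with an estimated correlation), as were basement membrane genes (12 fell, 2 rose, adjusted p = 0.0318, or 0.451 with an estimated correlation). Epithelial junction genes were called down (14 of 40 fell, 3 rose, adjusted p = 0.0396, or 0.495 with an estimated correlation), a call lost without 0 h replicate 2 (0.0548), 0 h replicate 4 (0.1) or BSA 36 h replicate 2 (0.102). The basement membrane call was also lost with only the groups compared (adjusted p = 0.0798), without BSA 36 h replicate 2 (adjusted p = 0.102) and without BSA 36 h replicate 3 (adjusted p = 0.0552). The largest rises were Spp1, a secreted matrix phosphoprotein (10.09±0.44, adjusted p = 9.6e-09), Tmem213 (at least 215.2-fold from 0 counts), Ccl20 (at least 175.7-fold), Klk6 and Reg3b, and the largest falls included Sbp (at least 1560.0-fold to 0 counts), Hbb-bs, Cytl1 and Fosb. EdgeR called 4916 genes, 2312 higher and 2604 lower.

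From 0 h to 36 h with FGF10, Cdh2 rose 6.05-fold (2.60±0.45, adjusted p = 0.00047) and Tnc by 4.74±0.38 (adjusted p = 1.7e-06), while Cdh1 did not pass (-0.28±0.18, adjusted p = 0.23) and Epcam fell by 0.59±0.18 (adjusted p = 0.0196). The Epcam call was lost without 0 h replicate 2 (adjusted p = 0.0555) or 0 h replicate 4 (0.0782). Snai1 (2.24±0.76, adjusted p = 0.0306) and Fn1 (1.49±0.38, adjusted p = 0.00804) rose, Zeb1 (-3.26±0.89, adjusted p = 0.0106) and Zeb2 (-3.05±0.51, adjusted p = 0.00034) fell, and Twist1 fell 7.25-fold (interval 2.19 to 37.7, 3 counts remaining, adjusted p = 0.0141, or 0.0801 without 0 h replicate 1). The Snai1 call was lost without 0 h replicate 1 (adjusted p = 0.108), 0 h replicate 2 (0.0501), 0 h replicate 4 (0.0657) or FGF10 36 h replicate 3 (0.133). Snai2 (0.29, adjusted p = 0.268) and Vim (0.21, adjusted p = 0.7) did not pass, and Fgfr2 fell by 2.76±0.21 (adjusted p = 5.2e-07). Krt5 (2.37±0.15, adjusted p = 1.3e-07) and Krt14 (2.59±0.20, adjusted p = 5.5e-07) rose.

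The partial EMT list rose from 0 h with FGF10 at 36 h (14 of 25 rose and 3 fell, adjusted p = 5.7e-05, or 0.0215 with an estimated correlation), with Thbs1 at 3.20±0.34 (adjusted p = 1.1e-05). Cholesterol genes rose (23 of 24, adjusted p = 1.9e-26, or 0.0215 with an estimated correlation), as did squamous genes (16 of 21 rose and 2 fell, adjusted p = 8.2e-13, or 0.0215 with an estimated correlation). Fatty acid genes rose (10 rose and 3 fell, adjusted p = 1.6e-05, or 0.0361 with an estimated correlation), with the desaturase Scd1 at 4.30±0.25 (adjusted p = 7.8e-08), and among cholesterol genes Msmo1 stood at 2.65±0.15 (adjusted p = 3.8e-08). Immune markers fell (15 of 18, adjusted p = 2.9e-13, or 0.0215 with an estimated correlation). The other calls were lost with an estimated correlation. Mitosis genes (12 of 40 rose, adjusted p = 1.2e-08, or 0.55 with an estimated correlation) and DNA replication genes (26 of 40 rose, adjusted p = 2.7e-08, or 0.55 with an estimated correlation) were called up. So were glycolysis (17 rose, adjusted p = 9.9e-08, or 0.445 with an estimated correlation) and ribosome biogenesis genes (23 rose, adjusted p = 2.9e-07, or 0.27 with an estimated correlation). Inflammatory genes were called up (15 rose, adjusted p = 0.00015, or 0.55 with an estimated correlation). Endothelial markers were called down (19 of 20 fell, adjusted p = 1.8e-05, or 0.501 with an estimated correlation), as were fibroblast markers (17 of 24 fell, adjusted p = 3.5e-05, or 0.501 with an estimated correlation). Hormone sensing markers were called down (13 of 19 fell, adjusted p = 8.4e-05, or 0.27 with an estimated correlation). Fen1 (1.58±0.36, adjusted p = 0.00333) and Anln, a cytokinesis gene (2.25±0.54, adjusted p = 0.00689), were among the 38 proliferation members that rose. That number was 80 of 80 without 0 h replicate 1, 11 without 0 h replicate 2, 16 without 0 h replicate 4, 14 without FGF10 36 h replicate 1, 23 without FGF10 36 h replicate 3 and 14 without FGF10 36 h replicate 4. It was 4 with only the groups compared, 11 with no filter on low counts and 78 in limma voom. Epithelial junction genes (6 rose and 12 fell, adjusted p = 0.111), EMT transcription factors (6 rose and 3 fell, adjusted p = 0.222) and mesenchymal effectors (12 rose and 13 fell, adjusted p = 0.268) were not called. The largest rises were Spp1 (11.45±0.46, adjusted p = 2.6e-09), Ccl20, Krtdap, Prl2c3 and Serpinb2, and the largest falls included Sbp, Cytl1, Inmt and Cd300lg. EdgeR called 7225 genes, 3504 higher and 3721 lower, or 3847 with only the groups compared (1647 higher and 2200 lower).

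From 0 h to 72 h with BSA, Cdh1 fell by 0.72±0.18 (adjusted p = 0.00973) and Epcam by 1.15±0.19 (adjusted p = 0.00038). The luminal keratins Krt8 (-0.98±0.23, adjusted p = 0.00551) and Krt18 (-1.33, adjusted p = 0.00366) fell, and Fn1 (2.42±0.39, adjusted p = 0.00055) and Snai1 (3.09±0.73, adjusted p = 0.00605) rose. Zeb2 (-0.29±0.44, adjusted p = 0.682), Zeb1 (-0.20, adjusted p = 0.879), Cdh2 (0.30±0.47, adjusted p = 0.696) and Vim (0.96±0.38, adjusted p = 0.0875) did not pass. Adipocyte genes were called up, 6 of 12 rising and 1 falling (median 1.32, adjusted p = 0.0306, but 0.54 with an estimated correlation and 0.0745 without 0 h replicate 4), with Lpl at 3.55±0.51 (adjusted p = 0.00036), Plin1 at 6.13±1.26 (adjusted p = 0.00336) and Adipoq at 6.11±1.26 (adjusted p = 0.004). Their summed level with BSA at 72 h (437.2 to 449.8 CPM) lay below 0 h replicates 1 and 2 (577 and 477.2) and above replicate 4 (78.9). Their geometric mean was 7.09 to 7.61 CPM against 0.948 to 2.53 at 0 h. Fgfr2 fell by 2.80±0.21 (adjusted p = 5.8e-07) and Etv4 by 2.29±0.35 (adjusted p = 0.00023). EMT transcription factors had 5 members rising and 0 falling and were not called (adjusted p = 0.0795), with Tcf4 (1.29±0.18, adjusted p = 0.00014) and Id2 (1.06±0.18) among them.

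Every list call from 0 h to 72 h with BSA was lost with an estimated correlation. Glycolysis genes were called up (24 of 30 rose, adjusted p = 4.2e-19, or 0.119 with an estimated correlation), with Slc16a3 at 6.36±0.62. Cholesterol (18 of 24 rose, adjusted p = 2.2e-13, or 0.119 with an estimated correlation) and squamous genes (12 of 21 rose, adjusted p = 4.8e-11, or 0.112 with an estimated correlation) were called up. So were fatty acid (8 rose, adjusted p = 0.00041, or 0.119 with an estimated correlation) and inflammatory genes (8 rose, adjusted p = 0.00211, or 0.668 with an estimated correlation). Partial EMT genes were called up (8 rose and 3 fell, adjusted p = 0.0213, or 0.119 with an estimated correlation), with Thbs1 at 2.25±0.32. Immune markers were called down (10 fell and 2 rose, adjusted p = 4.6e-07, or 0.17 with an estimated correlation), with Cd74 at -5.72±0.29. FGF and ERK feedback (14 of 29 fell, adjusted p = 0.00027, or 0.23 with an estimated correlation) and hormone sensing genes (8 fell, adjusted p = 0.0012, or 0.317 with an estimated correlation) were called down. Ribosomal protein genes were called down (14 of 34 fell, adjusted p = 0.0012, or 0.654 with an estimated correlation), such as Rpl32 (-0.79±0.16, adjusted p = 0.00238). Luminal markers were called down (9 of 22 fell and 4 rose, adjusted p = 0.025, or 0.317 with an estimated correlation), a call lost without 0 h replicate 2 (0.202) or BSA 72 h replicate 3 (0.0633). Epithelial junction genes were called down (11 fell and 4 rose, adjusted p = 0.0306, or 0.54 with an estimated correlation), a call lost without 0 h replicate 2 (0.052), 0 h replicate 4 (0.0746) or BSA 72 h replicate 3 (0.0584). Mitosis and DNA replication genes were not called (adjusted p = 0.0791 and 0.998), with 0 of 80 members rising and 1 falling, but 60 rising without 0 h replicate 1. Mesenchymal effectors had 8 rising and 8 falling, a median of -0.10 where the test pointed up (adjusted p = 0.646). The largest rises were Tmem213, Klk1, Ivl (9.77±1.37, adjusted p = 0.00037), Ttr and Cxcl13 (9.71±0.90, adjusted p = 1.8e-05), and the largest falls included Sbp, Hbb-bs, Fosb and R3hdml (-9.80±0.66, adjusted p = 9.7e-07). EdgeR called 4568 genes, 2210 higher and 2358 lower.

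From 0 h to 72 h with FGF10, Cdh2 rose by 2.80±0.45 (adjusted p = 0.00031), Tnc by 4.91±0.38 (adjusted p = 1.0e-06) and Fn1 by 2.04±0.38 (adjusted p = 0.00148). Snai1 rose by 3.57±0.72 (adjusted p = 0.0018), while Zeb2 fell by 4.25±0.57 (adjusted p = 6.6e-05) and Epcam by 0.86±0.18 (adjusted p = 0.00266). Cdh1 (-0.33±0.18, adjusted p = 0.184), Snai2 (0.26, adjusted p = 0.353) and Vim (0.49, adjusted p = 0.364) did not pass. Krt14 rose by 3.91±0.21 (adjusted p = 2.7e-08) and Krt5 by 3.11±0.16 (adjusted p = 1.8e-08). The next 5 calls held with an estimated correlation. Cholesterol (23 of 24 rose, adjusted p = 2.5e-32, or 0.0154 with an estimated correlation) and squamous genes (16 of 21 rose, adjusted p = 8.7e-18, or 0.0154 with an estimated correlation) rose. Fatty acid genes rose (12 members, adjusted p = 3.1e-07, or 0.0179 with an estimated correlation), as did partial EMT genes (14 of 25 rose and 2 fell, adjusted p = 5.7e-05, or 0.0154 with an estimated correlation), with Col17a1 at 1.69±0.16 (adjusted p = 3.2e-06). Immune markers fell (15 of 18, adjusted p = 8.7e-18, or 0.0154 with an estimated correlation). Cd74 stood at 8.78±0.491 CPM (-7.11±0.32, adjusted p = 5.1e-09).

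Other calls from 0 h to 72 h with FGF10 were lost with an estimated correlation. Glycolysis (15 rose, adjusted p = 1.9e-07, or 0.485 with an estimated correlation) and mitosis genes (3 rose, adjusted p = 2.9e-07, or 0.676 with an estimated correlation) were called up, with Ldha at 2.02. DNA replication genes were called up (2 rose, adjusted p = 5.7e-05, or 0.699 with an estimated correlation), such as Fen1 (1.14, adjusted p = 0.028). Of the 80 mitosis and DNA replication members 5 rose, but 80 without 0 h replicate 1, 0 without 0 h replicate 2, 1 without 0 h replicate 4, 2 without FGF10 72 h replicate 2, 3 without FGF10 72 h replicate 3 and 0 without FGF10 72 h replicate 4. Ribosome biogenesis genes were called up (8 rose, adjusted p = 0.018, or 0.676 with an estimated correlation), a call lost without 0 h replicate 1 (0.125) or FGF10 72 h replicate 4 (0.124). Hormone sensing (8 fell, adjusted p = 7.9e-05, or 0.297 with an estimated correlation) and endothelial markers (11 of 20 fell, adjusted p = 9.1e-05, or 0.569 with an estimated correlation) were called down. Fibroblast markers were called down (15 of 24 fell, adjusted p = 0.0005, or 0.571 with an estimated correlation). FGF and ERK feedback genes were called down (9 fell and 3 rose, adjusted p = 0.0316, or 0.569 with an estimated correlation), a call lost without 0 h replicate 4 (0.0525), FGF10 72 h replicate 2 (0.0625) or FGF10 72 h replicate 3 (0.068). Epithelial junction genes (5 rose and 13 fell, adjusted p = 0.082) and EMT transcription factors (7 rose and 2 fell, adjusted p = 0.247), with Foxc1 at 1.31±0.24 (adjusted p = 0.0009), were not called. The largest rises were Tmem213, Krtdap, Prl2c3, Spp1 and Ccl20, and the largest falls included Hbb-bs, Sbp, Dcpp3 and Cytl1. EdgeR called 5417 genes, 2507 higher and 2910 lower. All the contrasts with 0 h share the same 3 control libraries.

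Within the FGF10 arm from 36 h to 72 h, Krt14 rose by 1.33±0.19 (adjusted p = 0.00267) and Krt5 by 0.73±0.15 (adjusted p = 0.018), and the stromal receptor Pdgfra rose by 1.75±0.41 (adjusted p = 0.0427). Cdh1 (-0.05, adjusted p = 0.919), Cdh2 (0.20, adjusted p = 0.846), Zeb2 (-1.20, adjusted p = 0.35) and Snai1 (1.34, adjusted p = 0.261) did not pass. The largest rises were Cxcl13 (4.47±0.73, adjusted p = 0.0107), Wfdc17, Matn4, Brinp1 and the calcification inhibitor Mgp (3.32±0.56, adjusted p = 0.0113), which went from 49.7±32.9 to 497.7±65.9 CPM. The largest falls were the casein Csn3 (-3.58±0.57, adjusted p = 0.00789), the AP-1 factor Fosl1 (-2.63±0.54, adjusted p = 0.0203), the urokinase receptor Plaur (-2.58±0.32, adjusted p = 0.00182), Rbp7 and Pwwp3b. EdgeR called 346 genes, 257 higher and 89 lower, or 99 without FGF10 72 h replicate 2 and 109 without FGF10 72 h replicate 3. Counts of 161 with only the groups compared, 874 in limma voom and 777 in DESeq2 were found.

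Within the BSA arm from 36 h to 72 h no gene of the fixed panel passed, with Vim at 1.60±0.39 (adjusted p = 0.0834) and Zeb2 at 1.77±0.47 (adjusted p = 0.0958). Adipoq rose by 7.67±1.45 (adjusted p = 0.0484) and Nos2 by 3.36±0.52 (adjusted p = 0.0298), with Wfdc17 (2.87±0.45, adjusted p = 0.0313), the angiotensinogen gene Agt (2.78±0.56, adjusted p = 0.0472) and Brinp1 (2.39±0.41, adjusted p = 0.0313). Csn3 (-3.60±0.57, adjusted p = 0.0313), Apol9b (-2.60±0.50, adjusted p = 0.0323), Plaur (-1.86±0.31, adjusted p = 0.0313), Rtn1 (-1.37±0.28, adjusted p = 0.0473) and Spp1 (-1.36±0.28, adjusted p = 0.0499) fell. EdgeR called 85 genes, 59 higher and 26 lower, and each of the 10 named calls was lost when some 1 library was left out. The count was 30 without BSA 36 h replicate 1 and 0 without BSA 36 h replicate 2, BSA 36 h replicate 3 or any 1 of the BSA 72 h libraries. It was 217 with no filter on low counts and 578 in DESeq2 (304 higher and 274 lower). The balance turned with only the groups compared, with 442 higher and 740 lower of 1182, and in limma voom, with 1126 higher and 1460 lower of 2586. Of the 80 members of the DNA replication and mitosis lists, 64 and 35 fell in these settings, against 0 in the main test.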

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

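The tests of a shared fall of all other cells and of reads shared between Lars2 and Gm15564 were chosen only after the result was seen, as were the fits without 0 h replicate 1.

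The main test called no gene for a change of the FGF10 effect between 36 h and 72 h (DESeq2 called 19), but 13 of 34 lists passed at the preset correlation, and none with an estimated correlation (lowest adjusted p = 0.275). The median change of effect for immune markers was -1.20 (adjusted p = 4.9e-10), for adipocyte markers -2.03 (adjusted p = 4.9e-05), for endothelial markers -1.03 (adjusted p = 0.00057) and for fibroblast markers -0.85 (adjusted p = 0.00612). Proliferation lists went the other way, with DNA replication genes at 0.44 (39 of 40 positive, adjusted p = 0.00612) and mitosis genes at 0.65 (40 of 40, adjusted p = 0.00918). Ribosomal protein genes stood at 0.24 (adjusted p = 0.0002), oxidative phosphorylation genes at 0.13 (adjusted p = 0.00796), squamous genes at 0.41 (adjusted p = 0.0109) and WNT targets at 0.37 (adjusted p = 0.0109). Basement membrane genes stood at -0.27 (adjusted p = 0.00064), inflammatory genes at -0.27 (adjusted p = 0.00612) and stress and unfolded protein response genes at -0.19 (adjusted p = 0.00612).

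Proliferation genes stood higher with FGF10 at each time, yet 0 of 80 members of the replication and mitosis lists passed at 36 h and 2 at 72 h, and 0 passed at 72 h without any 1 of the 6 libraries compared or with 2_1 and 2_2 summed. The geometric mean over these members was 48.29 to 59.78 CPM with FGF10 and 26.5 to 40.17 with BSA at 36 h, 35.59 to 52.26 and 16.92 to 16.99 at 72 h, and 39.61 in 0 h replicate 1 against 5.94 and 4.36 in the other 0 h libraries. Without 0 h replicate 1, 28 members passed at 36 h and 77 at 72 h, while a fit of only the groups compared called 2 and 80. That fit drops all 0 h libraries and also those of the other time, so it does not isolate the 0 h libraries. A spread widened by 0 h replicate 1 is in line with the missing calls at 72 h, and at 36 h the reason is left open. The members vary together, with an estimated correlation of 0.579 for DNA replication and 0.679 for mitosis genes at 72 h without 0 h replicate 1. The list calls may therefore rest on fewer independent genes than their size. With these estimates both lists had an adjusted p of 0.0519. Partial EMT genes had the same adjusted p at a correlation of -0.003, so this value does not show what the shared variation costs.

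Markers of other cells stood lower with FGF10 than with BSA at 72 h. If BSA 72 h replicate 3 alone carried these cells, the difference would go without it, but the median over the lists stayed at -1.79, so this library alone does not account for the whole difference. A smaller share of all other cells in FGF10 samples was predicted to lower every type alike. The types differed instead (permutation p = 0.00062 of the Kruskal-Wallis statistic). Endothelial markers stood at -3.46, adipocyte markers at -3.42, immune markers at -1.70 and fibroblast markers at -1.43, or -2.72, -3.57, -1.77 and -0.90 without BSA 72 h replicate 3. The permutation treated members as independent, which they are not. Members within a type also differed, fibroblast markers running from -4.88 to 1.62, so a smaller share of other cells is not excluded. Adipocyte markers summed to 437.2, 442.3 and 449.8 CPM with BSA at 72 h, 43.53, 94.74 and 44.6 at 36 h, and 577, 477.2 and 78.9 at 0 h. With FGF10 they summed to 20.58, 26.97 and 28.53 at 36 h and 81.79, 30.24 and 15.84 at 72 h. For each type every BSA 72 h library summed higher than every BSA 36 h library. The FGF10 sums overlapped between the times for adipocyte and immune markers and were higher at 72 h for endothelial and fibroblast markers. The gap at 72 h thus went with a rise in the BSA arm after 36 h. No count of cells was used here, and whether the share of these cells or the level of their genes differed is left open.

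Lars2 stood at 1641±32.1 CPM with FGF10 and 364.7±73.9 with BSA at 72 h (2.17±0.41, adjusted p = 0.0115), where mt-Rnr2 had 1.12±0.33 (adjusted p = 0.0562). Gm15564, which shares 33 words of 20 bases with Lars2, followed it across 15 libraries with a correlation of 0.989, the highest of all tested genes. Fragments that matched several places were not counted, so reads identical in both genes would count for neither, and whether shared sequence explains the Lars2 counts is left open. More ribosomal RNA left in the libraries (Rn18s-rs5 and AY036118 at a mean of 0.43) and more mitochondrial RNA as a whole (13 messenger RNAs at a median of 1.11) could neither be ruled in nor out. Mitochondrial transcripts made up 4.31±0.363% of counts in this group, and whether FGF10 raised mitochondrial content was not tested.

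Grouping by chance was examined by splitting the same libraries in every other way for pairs of groups. For the change of effect only a random sample of the other splits was drawn. For each pair of groups 1 of 10 splits, the real one, gave as many called genes, and the highest count in another split was 93 for FGF10 against BSA at 36 h and 0 at 72 h. With 10 splits a share under 0.1 cannot be reached. For lists the real split was the highest for FGF10 against BSA at each time (16 against 12, and 17 against 16) and for BSA 36 h against 0 h (18 against 14). The median over the other splits of these comparisons was 10, 13 and 9 lists, so splits that mixed the groups also called many. For FGF10 36 h against 0 h and BSA 72 h against 0 h 3 of 10 splits called as many lists, and for FGF10 72 h against 0 h 2 of 10 did. The number of lists called at the preset correlation thus did not single out the real grouping. Every other split mixed the groups unevenly and kept part of the real difference, so its lists are no measure of chance. Mixing also adds the real difference to the spread within groups, which lowers the gene counts of the other splits. Which lists were called was not compared. For the change of effect the real count was 0, so all 25 splits gave at least as many by construction and say nothing about chance there.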

How the results depend on the processing

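The fits without 0 h replicate 1 of comparisons that do not use that group, and the list tests in several settings, were tests chosen only after the result was seen. Of 617 called values for named genes, 7980 of 8786 alternative values kept the call, 806 lost it and 0 turned direction, and 547 of the losses came from leaving out 1 library. These values pool all contrasts. For FGF10 against BSA, 43 of 63 named calls at 36 h and 64 of 96 at 72 h were lost under some alternative. Of 224 values that were not called, 298 of 3226 alternative values passed and 2 turned direction. Those were Top2a for BSA 72 h against 0 h, at -0.02 in the main test but 2.08 (adjusted p = 0.0286) in limma voom and 2.90 (adjusted p = 4.6e-06) without 0 h replicate 1. Leaving out 1 library gave -0.56 (without 0 h replicate 4) to 2.90 for Top2a. Of 90 list calls, 1005 of 1112 alternative values kept the call and 107 lost it, 70 with an estimated correlation.

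Size factors and the count filter moved no count of called genes by more than 1.5 times. With only the groups compared, counts were 78 for FGF10 against BSA at 36 h and 5025 at 72 h, 3847 for FGF10 36 h against 0 h, 161 for FGF10 72 h against 36 h and 1182 for BSA 72 h against 36 h. For the same comparisons save that of FGF10 36 h with 0 h, limma voom gave 1415, 4824, 874 and 2586 and DESeq2 1082, 1912, 777 and 578, with 19 for the change of the FGF10 effect. The main test pools its spread over the 5 groups, and the cause of the other shifts was not tested. With the libraries 2_1 and 2_2 summed, which leaves BSA 72 h with fewer samples, 277 genes were called at 72 h and 0 for BSA 72 h against 36 h, and without a filter 217 were called for the latter. With an estimated correlation 4 lists were called at 36 h, 6 at 72 h, 5 for each FGF10 group against 0 h and 0 for each BSA group against 0 h. Without a filter 20 lists were called for BSA 72 h against 0 h.

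Samples with the same replicate number deviated together in part. Their median correlation was 0.0266 over 21 pairs (-0.158 to 0.449, 9 above 0.1) against -0.0121 over 69 other pairs (10 above 0.1), and the replicate 1 pairs had 0.107, 0.169 and 0.449. The same-number pairs of BSA 36 h with FGF10 36 h had 0.449 for replicate 1 and 0.286 for replicate 3. Because not every pair passed 0.1 and no label says what a number shares, the main test has no pairing. Pairing of some samples is not excluded, least of all at 36 h. A replicate block kept 319 of the 425 genes called for FGF10 against BSA at 36 h. With a replicate block, counts were 479 and 1085 for FGF10 against BSA, 1 for the change of effect, 5387, 7580, 4128 and 5994 against 0 h for BSA 36 h, FGF10 36 h, BSA 72 h and FGF10 72 h, 671 for FGF10 72 h against 36 h and 107 for BSA 72 h against 36 h. Of the 80 proliferation members, the block called 63 for FGF10 72 h against 0 h (5 without it) and 75 for FGF10 36 h (38 without it). Lists called with the block were 15, 20, 20, 14, 14 and 15 in that order without the changes between times.

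Leaving out 1 library gave 127 to 852 genes for FGF10 against BSA at 36 h, 148 to 1857 at 72 h, 0 to 0 for the change of effect, 3707 to 5029 for BSA 36 h against 0 h, 5875 to 6919 for FGF10 36 h, 3256 to 4208 for BSA 72 h, 3952 to 5387 for FGF10 72 h, 99 to 323 for FGF10 72 h against 36 h and 0 to 30 for BSA 72 h against 36 h. Lists called ran from 14 to 18, 18 to 21, 17 to 20, 13 to 15, 12 to 15 and 12 to 14 for the comparisons that had list tests, in the same order. Fewer samples were used in each. At this depth and with 3 samples per group 43 of 100 simulated 2-fold changes were found, and how depth alone limits this was not tested.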

Other observations

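The list tests without 0 h replicate 1 were tests chosen only after the result was seen.

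Several genes that carry a named function outside the EMT question stood far apart between groups. R3hdml stood at 139±49.9 CPM at 0 h, 0.693±0.601 with BSA and 14.9±5.53 with FGF10 at 36 h, and 0.148 with BSA at 72 h. Csn3, a casein, stood at 1017±305.9 CPM with BSA and 1236±8.1 with FGF10 at 36 h, then at 83.8±26.2 and 103.6±51.5 at 72 h. Plaur, the urokinase receptor, fell over the same time in both arms, to 13.3±1.03 CPM with BSA and 13.2±2.33 with FGF10. Spp1 went from 0.405±0.314 CPM at 0 h to 493.6±5.02 with BSA and 1265±416 with FGF10 at 36 h.

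Fgfr2, whose annotated span is unusually wide, had log2 differences from 0 h of -2.86, -2.76, -2.80 and -3.04 in the later groups, while the FGF target genes Etv4 and Dusp6 stood higher with FGF10 than with BSA at each time. Cxcl13, a chemokine for B cells, stood at 239.6±39.2 CPM with BSA and 22.8±12.5 with FGF10 at 72 h against 0.229 at 0 h. Zeb2 stood at 7.61±5.01 CPM at 0 h, 6.11±2.13 with BSA at 72 h and 0.386±0.172 with FGF10 at 72 h. At 36 h Zeb2 was called lower than at 0 h in both arms. Immune markers summed to 1975, 2257 and 2541 CPM at 0 h. By 36 h their sums were 249.2, 253.2 and 287.8 with BSA and 129.9, 118.8 and 295.7 with FGF10. At 72 h they were 519.5, 554.3 and 463.1 with BSA and 180.3, 152.8 and 106.9 with FGF10. Which cells held the Zeb2 transcripts was not tested.

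The Cdh2 rise with FGF10 came with no called fall in Cdh1. The partial EMT list kept its call at each time with an estimated correlation, but not when 0 h replicate 1 was also left out (adjusted p = 0.0704 at 36 h and 0.0519 at 72 h). No test here separates a change within epithelial cells from a change in which cells were present.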
